A study of Homo sapiens with 4 samples.

How the data were processed

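Mononuclear cells of human blood, from a number of donors that the labels do not give, were profiled as 2 CITE-seq libraries, each deposited as an RNA table and an ADT table (4 samples in all). The labels assign batch 1 to a 2-fold and batch 2 to an 8-fold ADT dilution. Each dilution thus had 1 library, so dilution and batch cannot be separated, nor can any part that ADT sequencing depth has in a difference. According to the labels' protocols, cells were sorted and made into droplet libraries with the 10x Genomics 3' chemistry. Reads were processed with Cell Ranger against GRCh38, per the submitters' processing notes, which name no version and no settings. The deposited values are raw UMI counts per gene or antibody and cell: they were whole numbers whose totals differed between cells. The RNA tables hold 36601 genes, and 163 antibodies were counted in the ADT tables. Both tables of a library list the same barcodes in the same order, and every barcode had at least 501 detected genes, so the barcodes had been filtered before deposit by a rule the labels do not state. Gene names were used as the files give them, and no genome or annotation was needed.

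Cells were kept with at least 200 detected genes and under 20% mitochondrial UMIs, which removed 51 and 64 barcodes, and when Scrublet, run on each RNA library, did not call them doublets (7 and 14 barcodes). This left 1529 and 2034 cells. RNA counts of both libraries were scaled to 10000 per cell, log-transformed and reduced to 30 principal components of 2000 variable genes without integration. Leiden clustering used 15 neighbours and resolution 1. A cluster took the class whose fixed markers had the highest mean log2 fold over other cells (20 CPM added). It needed at least 3 markers detected in 20% of its cells and no class with more markers among its 10 top genes. Clusters that stayed unnamed or held a second class were clustered once more at resolution 0.5. The fixed markers were set before the data were examined; this naming rule, the 20% limit and the second round were set after the clusters had been seen. A low-UMI sub-cluster of 41 cells (17 in the 2-fold library and 24 in the 8-fold library) and a cycling one of 12 (2 and 10) were left unnamed. Classes are called "X-like" because they rest on RNA markers alone; protein counts played no part in them.

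For each antibody, the summed UMIs were divided by the number of cells, and the ratio of the libraries was taken with an exact conditional Poisson interval. Antibodies entered with at least 100 UMIs in each library. For 44 lineage antibodies, each with a class that should carry the protein and one that should lack it, the fold between classes and the area under the ROC curve were computed within each library from UMI counts, with ties counted equally for both classes. A class with fewer than 10 cells in a library gave no value. Gates called a cell positive above the 99th percentile of a negative class: B-like cells for CD3, CD4, CD8, CD56 and CD16, and T-like cells for CD20 and CD14. T cells had to be CD3 positive and CD14 negative, monocytes CD14 positive and CD3 negative, and NK cells negative for CD3 and CD14 and positive for CD56 or CD16. All of these gates also required that 1 further antibody of the panel be negative, which is not reported here. Protein and RNA were correlated across cells by Spearman's coefficient of counts per total. Shares have exact binomial (Clopper-Pearson) intervals, sums exact Poisson intervals and medians order-statistic intervals, all at 95%. UMIs count molecules, but none of these intervals covers differences between donors, stainings or library preparations.

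RNA was compared between libraries as CPM of UMIs summed per class, with 1 UMI added to each sum before taking log2. Correlations and SDs used genes with at least 50 UMIs over both libraries, and gene sets those with at least 20. Of the 11 gene sets fixed before the data were examined, each with at least 3 such genes was given its median log2 ratio and its percentile among 10000 random lists matched on mean expression in 20 bins. Poisson counting was simulated in 20 draws. No p-value or standard error was computed and no gene was called changed, since cells of 1 library are not replicates. Named antibodies were the 10 with the largest and the 10 with the smallest ratio, the isotype controls as a group and the lineage list. Named genes were the 10 highest and the 10 lowest log2 ratios per class among genes with at least 50 UMIs, and members of the fixed sets. Genes of the Y chromosome and of X inactivation, HLA, immunoglobulin, T cell receptor and KIR genes, and some others whose level varies strongly between people, were left out of these rankings. The 30 antibodies compared over T-like clusters, and the platelet proteins of the closing section, were chosen outside this rule.

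The steps were tested on simulated data. Among 9956 genes drawn from the T-like sums, 200 were changed, and changes of 2-fold and 4-fold were recovered as median log2 ratios of 1.00 and 2.00. A list of genes changed 2-fold lay at percentile 100, and 4 of 100 unchanged lists lay outside the central 95%. Genes were drawn independently there, so this share does not cover sets whose genes vary together or lie in a few cells. All of 3463 cells drawn from the summed class profiles received their own class, an easy case, and 95.8% of intervals held a simulated 4-fold antibody ratio. Alternatives covered the filters on cells and doublets, T-like cells alone, the highest-ADT cells, thinning of the deeper ADT library, clustering resolution, separate clustering, the gate rule, scaling and the minimum counts. The analysis used Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and python-igraph 0.11.9.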

Results

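CITE-seq data were collected from mononuclear cells of human blood. The method reads RNA and antibody-derived tags (ADTs) from the same droplets as unique molecular identifiers (UMIs). The panel held 163 antibodies, 9 of them isotype controls. The 2 libraries differed in antibody dilution: batch 1 had been stained at a 2-fold dilution and batch 2 at an 8-fold dilution. Each group held 1 library, so dilution and batch were the same split, no difference had a replicate check and no test was possible. The 2-fold library held 1587 cell barcodes with 11983233 RNA UMIs and 3814190 ADT UMIs. The 8-fold library held 2112 barcodes with 16054040 RNA UMIs and 2292870 ADT UMIs. After filtering, 1529 and 2034 cells remained, with medians of 7306 and 7177 RNA UMIs per cell. All intervals are 95% intervals. The Poisson intervals of sums and the exact binomial intervals of shares cover counting error only, and those of sums leave out the spread between cells. The intervals of medians, from order statistics, reflect the spread over the cells or antibodies that the median was taken from.

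Both libraries held the main mononuclear classes of blood at similar shares, as named from RNA alone. T-like cells made up 54.2% (51.7 to 56.7) of the 2-fold library and 56.2% (54.0 to 58.4) of the 8-fold library. Classical monocyte-like cells followed with 19.6% (17.6 to 21.6) and 16.4% (14.8 to 18.1), and NK-like cells with 12.8% and 13.5%. B-like cells made up 6.02% and 6.44%, platelet-like cells 3.27% and 3.10%, and nonclassical monocyte-like cells 1.57% and 1.43%. Rare dendritic-like cells numbered 7 and 14, plasmacytoid dendritic-like cells 7 and 3, and progenitor-like cells 7 and 9. The intervals of the libraries overlapped for each of these 9 classes, which does not show that the shares are equal. The classical monocyte-like and plasmacytoid dendritic-like shares each lay outside the interval of the other library. No cluster was named as plasma cells, erythroid cells, neutrophils or basophils. Cells in unnamed clusters were 1.24% and 1.67% of the libraries. The labels say that the cells had been sorted but not on what, so the shares describe the sorted cells.

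The question the design poses is how antibody dilution affected the protein signal of these cells. ADT UMIs per cell were higher in the 2-fold library, with medians of 1668 (1631 to 1713) against 637 (623 to 648), a ratio of 2.62, while RNA UMIs per cell had a ratio of 1.02. Over the 163 antibodies, the median ratio of mean UMIs per cell was 2.46 (2.21 to 2.82). The largest ratios were those of the Fc receptor CD32 (4.91, 4.76 to 5.06), the integrin chain CD11a (4.33), CD8 and CD7 (both 4.22) and the MHC class I antibody HLA-A-B-C (4.10). CD11c, CD3, CD4, CD44 and HLA-DR-DP-DQ completed the 10 largest, at 4.05 to 4.10. Ratios near 1 were found for the endothelial adhesion molecule CD146 (1.06, 0.976 to 1.15), the transferrin receptor CD71 (1.09), the T cell inhibitory receptor CD223 (1.15) and the macrophage lectin CD169 (1.17). The isotype controls, which have no target on human cells, had ratios of 1.0996 to 1.30. They averaged 5.33 UMIs per cell together in the 2-fold library and 4.42 in the 8-fold library, which was 0.220% (0.216 to 0.225) and 0.411% (0.402 to 0.419) of all ADT UMIs.

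CD85j and CD354, 2 receptors of myeloid and other leukocytes, had ratios below 1 over all cells, of 0.0553 and 0.135. A single T-like cell of the 8-fold library, with 343483 ADT UMIs, held 97.4% of the CD85j UMIs and 94.3% of the CD354 UMIs of that library. Without the 1% of cells with the most ADT UMIs in each library, the ratios were 2.06 (2.00 to 2.12) for CD85j and 2.37 (2.24 to 2.497) for CD354. Among T-like cells alone, the median ratio over antibodies was 1.30 (1.19 to 1.44). The myeloid proteins CD32 and CD11c had ratios of 0.790 (0.704 to 0.885) and 0.900 (0.732 to 1.105) there, whereas CD3 and CD4 had 4.47 and 4.37. As shares of all ADT UMIs, the median ratio was 1.096 (0.982 to 1.25), and CD146, CD71, CD223 and CD169 lay below 1, at 0.471 to 0.519. The single T-like cell named above held 15.7% of all ADT UMIs of the 8-fold library. It thus lowered the shares of most other antibodies in that library and raised their ratios.

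**Figure D1:**
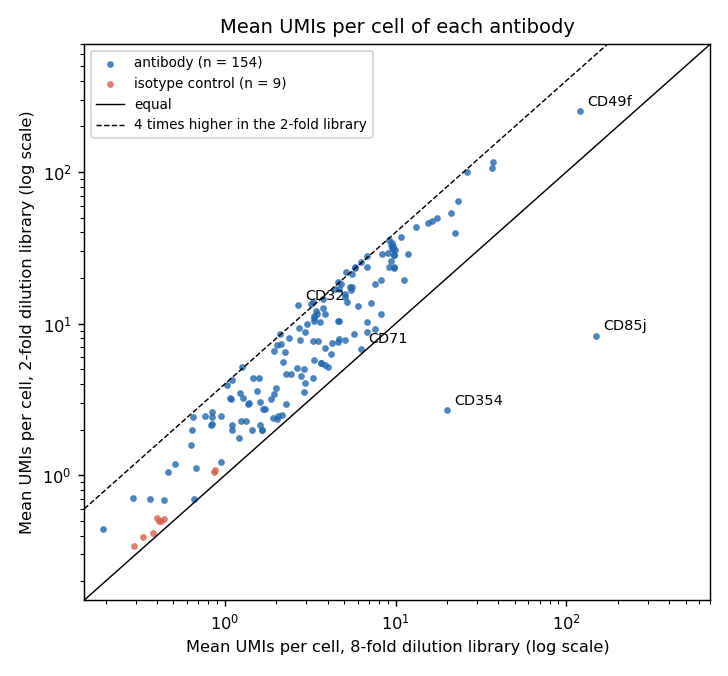
Mean UMIs per cell of each of the 163 antibodies in the 8-fold library (x axis, log scale) and the 2-fold library (y axis, log scale), with isotype controls in red, a solid line at equal means and a dashed line at a ratio of 4. Isotype controls lie just above the line of equality, and CD85j and CD354 lie below it because of 1 cell of the 8-fold library.

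Lineage proteins were higher in the 2-fold library on the cells that carry them and closer to level on cells that do not. Of the 44 lineage antibodies fixed in advance, 40 had at least 10 cells of both classes in both libraries. In the positive class their ratio had a median of 3.87, from 1.39 to 5.65. In the negative class the median was 1.12, from 0.416 to 2.18, and the positive class had the higher ratio for 40 of 40. CD3, the signalling part of the T cell receptor complex, gave 41.3 UMIs per T-like cell in the 2-fold library and 9.25 in the 8-fold library. B-like cells held 0.707 and 0.954 CD3 UMIs. The T-like over B-like fold of CD3 was thus 58.5 (45.85 to 75.8) and 9.69 (8.12 to 11.7). In the 8-fold library 4 B-like cells held 62 of the 125 B-like CD3 UMIs, and without them, a choice made after seeing the data, the fold was 18.6 (14.6 to 24.3). CD20, a membrane protein of B cells, was 73.7 (67.0 to 81.2) times higher in B-like than in T-like cells in the 2-fold library and 20.7 (18.7 to 23.0) times in the 8-fold library. CD14, the lipopolysaccharide coreceptor of monocytes, was 48.2 and 13.5 times higher in classical monocyte-like than in T-like cells. CD16, the Fc receptor of NK cells, gave 136 and 26.9 UMIs per NK-like cell against 2.07 and 1.87 per B-like cell.

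The antibodies differed in how far their positive-class signal stood apart between libraries. T-like proteins had the highest class median ratio, 4.30, followed by B-like proteins with 3.90, NK-like proteins with 3.87, platelet-like proteins with 3.44 and classical monocyte-like proteins with 3.42. CX3CR1, the fractalkine receptor, had a ratio of 1.39 (1.31 to 1.48) in NK-like cells, and the myeloid lectin CLEC12A had 1.70 (1.67 to 1.74) in classical monocyte-like cells. The haemoglobin scavenger receptor CD163 and the B cell receptor chain CD79b also had low ratios, of 2.31 and 2.39. In the 8-fold library the positive class held 7.97 (CX3CR1), 2.80 (CD163) and 3.23 (CD79b) UMIs per cell. Their negative classes held 3.22, 0.739 and 1.30 UMIs, and the ratios are not corrected for this background. CLEC12A stayed at 37.6 UMIs per classical monocyte-like cell in the 8-fold library, against 0.230 per T-like cell. HLA-DR had the highest ratio, 5.65 (5.30 to 6.03), in B-like cells. Its fold over T-like cells in the 8-fold library, 1.95, was set in part by the single high-ADT cell, which held 38.3% of the HLA-DR UMIs, and was 6.43 without the 1% of cells with the most ADT UMIs. The HLA-DR ratio in T-like cells, its negative class, was 0.763 over all cells and 2.52 without that 1%, which made it the highest negative-class ratio.

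**Figure D2:**
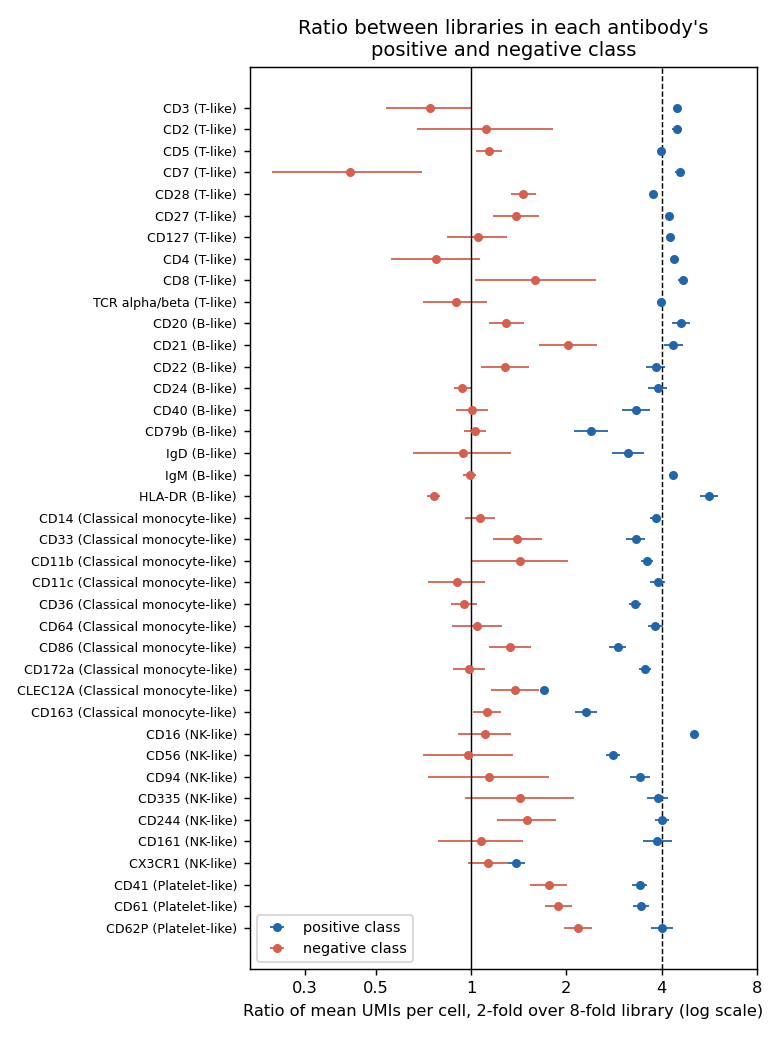
Ratio of mean UMIs per cell between the 2-fold and 8-fold libraries (x axis, log scale) for 39 of the 40 lineage antibodies, in the class that carries the protein (blue) and in the class that does not (red), with 95% counting intervals as bars. Over all 40, positive classes have a median of 3.87 and negative classes one of 1.12; lines mark ratios of 1 and 4.

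Separation of positive from negative cells was measured by the area under the ROC curve (AUC) of the UMI count, which is 1 for complete separation. The AUC was higher in the 2-fold library for 37 of the 40 antibodies, with medians of 0.985 and 0.923. CD161, a C-type lectin receptor of NK cells, differed most, with 0.929 against 0.701 between NK-like and B-like cells. CD79b separated B-like from T-like cells with 0.918 against 0.763, and CD163 separated classical monocyte-like from T-like cells with 0.935 against 0.787. The alpha/beta T cell receptor antibody followed with 0.964 against 0.826. The B cell proteins CD21 (0.980 against 0.988) and CD22 (0.986 against 0.987), and CLEC12A, had slightly higher values in the 8-fold library. Among CD20, CD14, CD16 and CLEC12A, the lowest value in either library was 0.984, for CD14 in the 8-fold library. CD8 gave 0.586 and 0.584, and the median T-like cell held no CD8 UMI.

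**Figure D3:**
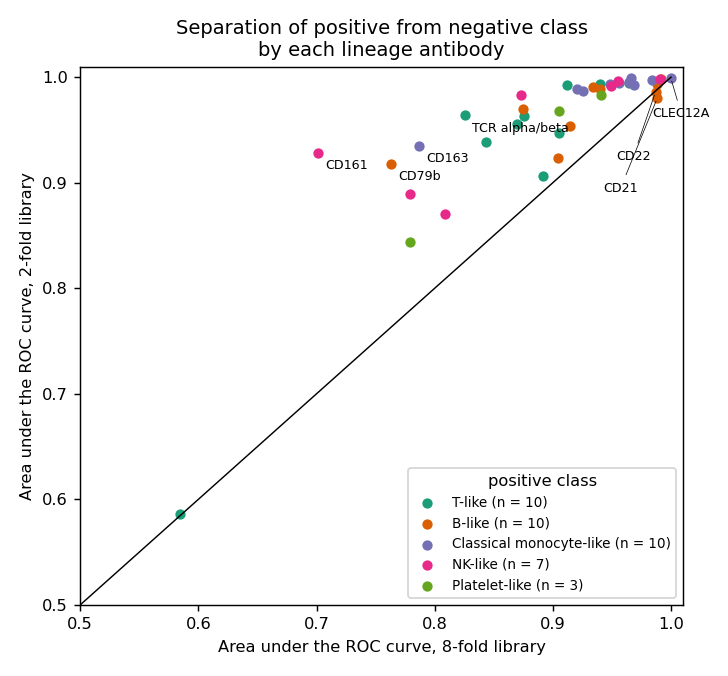
Area under the ROC curve of 40 lineage antibodies in the 8-fold library (x axis) and the 2-fold library (y axis), coloured by positive class, with a line at equal values. Points above the line (37 of 40) separate their classes better in the 2-fold library, and CD161 lies farthest from it.

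Gates were then set as a cytometrist would, with a cell called positive above the 99th percentile of a class that lacks the protein. NK-like cells fell in the NK gate, which takes CD56 or CD16, in 97.4% of cases in both libraries. CD56 was called on 97.4% (94.1 to 99.2) of them in the 2-fold library and 70.4% (64.7 to 75.8) in the 8-fold library. CD16 was called on 98.5% and 96.4%. Classical monocyte-like cells fell in the monocyte gate in 74.6% (69.3 to 79.4) and 80.2% (75.6 to 84.4). CD14 itself was called on 99.3% and 81.1% of these cells. CD3, which this gate excludes, was called on 23.7% and 0.60% of them. T-like cells fell in the T gate in 98.4% (97.3 to 99.2) and 27.6% (24.99 to 30.2). CD4, the coreceptor of helper T cells, was called on 79.6% (76.7 to 82.3) and 52.4% (49.5 to 55.3) of T-like cells. CD8, that of cytotoxic T cells, was called on 18.1% (15.5 to 20.9) and 17.9% (15.8 to 20.3). T-like cells with neither protein were 4.46% and 30.7%, and those with both 2.17% and 1.05%. The CD3 threshold was 3 UMIs in the 2-fold library and 11 in the 8-fold library, where 4 B-like cells held more than 5 CD3 UMIs. With those cells left out of the thresholds, a choice made after seeing the data, 91.3% (89.5 to 92.8) of T-like cells of the 8-fold library fell in the T gate and 79.9% (77.4 to 82.2) were CD4 positive, while its classical monocyte-like cells fell in the monocyte gate in 66.5% (61.1 to 71.5). With the 2-fold library thinned to the mean or the median ADT total of the other, its monocyte value was 85.3% or 90.3%. In the 8-fold library, CD4 was called on 9.35% of T-like cells with called doublets kept, and gates from a Gaussian mixture took in 43.7% of T-like and 46.4% of NK-like cells.

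The genes of the gated proteins were detected in a larger share of gated cells than of the class that lacks the protein, in both libraries. This contrast between classes is partly built in, since the RNA markers that named the classes include CD3E, CD4, CD8B, MS4A1, CD14 and NCAM1. The contrast with ungated cells of the same class is not. CD3E RNA was found in 97.1% and 99.1% of CD3-positive T-like cells, against 5.43% and 6.87% of B-like cells, but also in 96.8% of the 822 T-like cells of the 8-fold library outside the CD3 gate. CD8B RNA was found in 78.0% and 81.0% of CD8-positive T-like cells and in 0 of 92 and 0 of 131 B-like cells, with upper limits of 3.93% and 2.78% for the share with a detected UMI. T-like cells without the CD8 protein had it in 0.295% and 0.746% of cases. CD4 RNA was seen less often, in 46.2% and 48.1% of CD4-positive T-like cells, against 3.26% and 3.05% of B-like cells and 1.18% and 25.6% of other T-like cells. MS4A1, the gene of CD20, was found in 100% of CD20-positive B-like cells of both libraries and in 3.62% and 4.11% of T-like cells, but also in all 15 B-like cells of the 8-fold library without the protein. The genes of CD14 and CD16 were found in 93.9% and 93.0% of CD14-positive monocyte-like cells and in 98.4% and 96.6% of CD16-positive NK-like cells; 98.4% of the 63 CD14-negative monocyte-like cells of the 8-fold library also had CD14 RNA. NCAM1, the gene of CD56, was found in 40.5% and 49.7% of CD56-positive NK-like cells, and in 29.6% of the 81 others in the 8-fold library. Median depths were 7653 and 7687 RNA UMIs per T-like cell and 6182 and 6050 per B-like cell.

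Across cells, each lineage protein correlated with its own RNA more closely in the 2-fold library for 38 of 44 pairs, with median Spearman coefficients of 0.439 and 0.361. CD127, the interleukin-7 receptor, had the closest relation with its gene IL7R, at 0.834 and 0.743. CLEC12A was at 0.681 and 0.672. CD161 with KLRB1 stood at 0.664 against 0.410, and CD163 with its RNA at 0.316 against 0.0966. CD8, CD22, CD56, CD20 and IgD were among those with slightly higher coefficients in the 8-fold library. The cells of a library are not replicates, so these coefficients describe each library.

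Within T-like cells, surface proteins of RNA-defined clusters mostly differed in the same direction at both dilutions. Over 8 clusters and 30 antibodies, a set chosen after the files were seen but before these values, 216 of 240 folds over the other T-like cells had the same direction in both libraries. Of 88 folds beyond 2 in either direction in the 2-fold library, 86 kept their direction and 79 were smaller in the 8-fold library. These folds were picked by their size in the 2-fold library, so the 79 cannot tell an effect of dilution from that choice. Cluster 11, led by CD8B, CD8A and the naive-cell genes CCR7 and LEF1, had 12.7 (12.4 to 13.1) and 14.3 (13.5 to 15.1) times the CD8 of other T-like cells and 0.052 and 0.104 times their CD4. Its CD45RA, an isoform of naive cells, was 2.14 and 2.10 times higher, and its CD45RO, an isoform of memory cells, was 0.328 and 0.457 times as high. Cluster 9.2, led by IL2RA and FOXP3, had RNA of all 5 regulatory T cell markers. It had 3.52 (2.97 to 4.15) and 4.36 (3.59 to 5.27) times the CD25, the protein of IL2RA, and 0.148 and 0.297 times the CD127. It also carried more of the chemokine receptor CD194, by 2.67 and 3.30 times.

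The other T-like clusters also differed in surface proteins. Cluster 4, led by GZMK, CCL5 and KLRG1, carried 26.1 (21.1 to 32.3) and 9.43 (7.35 to 12.1) times the TCR-Vd2 of other T-like cells, a receptor chain of gamma-delta T cells, and 6.34 and 5.51 times the KLRG1. The median cell of that cluster had no TCR-Vd2 UMI in either library. Cluster 3, led by KLRB1, MAF and CCR6, carried 4.59 (4.26 to 4.94) and 2.77 (2.47 to 3.09) times the CD161, the protein of KLRB1, and 4.03 and 2.41 times the CD196, the protein of CCR6. Cluster 2, led by CCR7, had 1.24 and 1.34 times the CD45RA and 0.469 and 0.572 times the CD45RO. Cluster 9.0 had the opposite arrangement, with 0.290 and 0.461 times the CD45RA and 1.75 and 1.44 times the CD45RO.

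**Figure D4:**
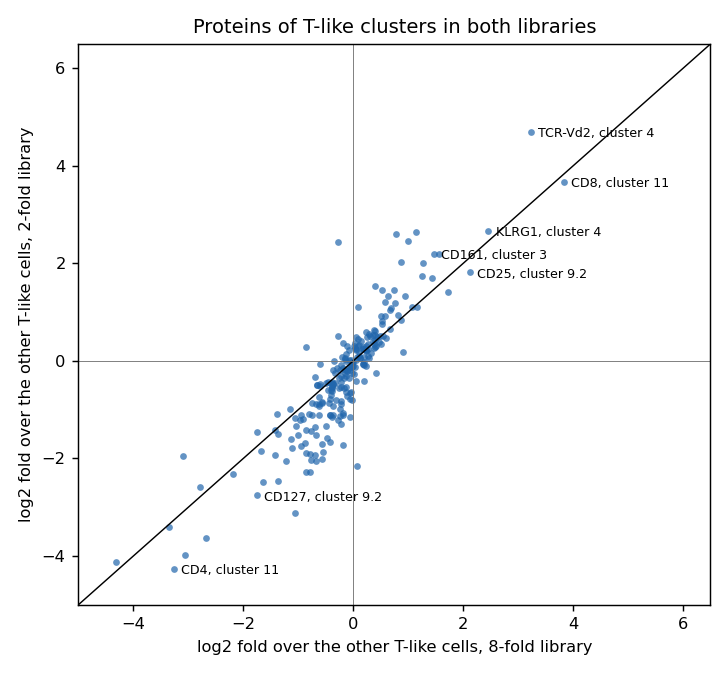
Log2 fold of each of 30 proteins in each of 8 T-like clusters over the other T-like cells, in the 8-fold library (x axis) and the 2-fold library (y axis), with a line at equal values. Of 240 points, 216 lie on the same side of 0 in both libraries.

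The RNA of the libraries was close within each class. Across genes with at least 50 UMIs, which are not independent replicates, the libraries were compared by the Pearson correlation of log2 CPM. It was 0.994 in T-like, 0.981 in NK-like, 0.965 in B-like and 0.987 in classical monocyte-like cells. The SD of the log2 ratio between libraries was 0.22 in T-like cells, where Poisson counting alone gave 0.21, and 0.38 against 0.29 in B-like cells. Among genes with at least 50 UMIs, the largest T-like differences were in genes of few counts, such as ACOX3 (44 UMIs in the 8-fold library against 13, log2 1.23) and DAG1 (30 against 55, log2 -1.31). In NK-like cells they were ST3GAL5, a ganglioside synthase, with 63 against 16 UMIs and ABCF2 with 19 against 31. For a gene set, the median log2 ratio of the 8-fold over the 2-fold library is given with its percentile among 10000 expression-matched random lists. The random lists do not keep genes that vary together, as those of a set may, so a percentile is not an error rate.

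Cytotoxic genes stood out in classical monocyte-like cells, where 11 of 11 were higher in the 8-fold library, with a median log2 of 1.99 (percentile 100). GNLY had 270 UMIs against 29 (log2 2.98), GZMB 90 against 7 (log2 3.31) and KLRD1 57 against 9 (log2 2.34), and 5 cells held 84.4%, 77.8% and 73.7% of these 8-fold library counts. With called doublets kept, the set median was 1.06 while GZMB and PTGDS, a prostaglandin synthase of NK cells, turned to log2 -0.38 and -2.14. Inflammatory genes had a median of -0.49 (percentile 0, 7 of 9 lower), with CXCL8 at 14 UMIs against 37 and IL1B at 45 against 101, 83.8% and 68.3% of the 2-fold library counts lying in 5 cells. With every barcode kept the inflammatory median was -0.12. Interferon genes (-0.094, percentile 0.97, 14 of 19 lower), platelet genes (-0.12, percentile 0.25) and ribosomal protein genes (-0.034, percentile 0.77) were slightly lower and naive T genes slightly higher (0.26, percentile 99.1). Without the 5% of cells with the most RNA UMIs, a choice made after seeing the data, the platelet median was -0.56 and the cytotoxic median 1.96. Immediate early, heat shock, mitochondrial and MHC class II genes lay between percentiles 3.16 and 87.3.

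Several of the B-like genes with the lowest ratios are known from antibody-secreting cells; they were picked by their ratio, and no fixed set covers them. TXNDC5 had 171 UMIs against 38 (log2 -2.51), XBP1, a regulator of the secretory program, 99 against 23 (log2 -2.43), TNFRSF17, the B cell maturation antigen, 52 against 13 and MZB1 143 against 52. In the 2-fold library, 5 cells held 91.8%, 96.0%, 84.6% and 79.0% of these counts. Further UMIs of TXNDC5 and MZB1 lay outside the B-like class, in the unnamed cycling sub-cluster: 159 of TXNDC5 and 70 of MZB1 in its 2 cells of the 2-fold library, and 100 and 78 in its 10 cells of the 8-fold library. In each library these MZB1 UMIs lay in 1 cell. The remaining cells held 94 and 105 UMIs of TXNDC5, 44 and 39 of MZB1, and 1393 and 1836 of XBP1. Without the 5% of cells with the most RNA UMIs, TXNDC5 and XBP1 turned to log2 0.15 and 0.47. AQP3, a water and glycerol channel, had 55 UMIs against 4, all 55 in 3 cells. Platelet genes were lower in the 8-fold library (PPBP 42 UMIs against 78, PF4 21 against 40; median -1.28, percentile 0, 4 of 4) and naive T genes higher (IL7R 40 against 7; median 0.56, percentile 99.99, 6 of 8). The B-like naive T median was 0.16 over genes with at least 100 UMIs, and the platelet median -0.34 with every barcode kept. The interferon, immediate early, heat shock, ribosomal protein, mitochondrial and MHC class II sets lay between percentiles 16.8 and 94.9.

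T-like and NK-like cells had smaller set differences. In T-like cells, cytotoxic genes had a median of -0.11 (percentile 0.04, 9 of 13 lower) and ribosomal protein genes one of -0.016 (percentile 0.005, 73 of 83 lower). Without the 5% of cells with the most RNA UMIs the cytotoxic median was 0.0056, and with each library clustered by itself the ribosomal median was 0.0015. The other 8 T-like sets lay between percentiles 11.1 and 93.6. The largest T-like cluster of the 2-fold library was cluster 2, with 188 cells against 176 in cluster 10. That of the 8-fold library was cluster 10, with 294 cells against 200 in cluster 2. Both clusters had CCR7, TCF7 and LEF1 among their top genes. In NK-like cells, naive T genes (0.32, percentile 99.8, 7 of 8 higher) and platelet genes (0.48, percentile 98.2, 3 of 4 higher) stood above their random lists. The NK-like naive T median was -0.0064 with called doublets kept. The T cell gene CD3D had 44 UMIs against 14 in NK-like cells, 54.5% of the 44 in 5 cells. The other 8 NK-like sets lay between percentiles 2.7 and 83.5. Haemoglobin genes had too few counted members for a value in any class, as had cytotoxic and inflammatory genes in B-like cells.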

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

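Of the tests in this part, those of unspecific binding and of random capture were chosen only after the result was seen, as were the antibodies CD42b, CD9 and CD49f; the test of attached platelets was written before its value was known.

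Proteins of platelets were found on classical monocyte-like cells, in antibodies outside the lineage list. The platelet glycoprotein CD42b averaged 82.3 UMIs per classical monocyte-like cell in the 2-fold library and 28.7 in the 8-fold library, the tetraspanin CD9 averaged 405 and 126, and the integrin chain CD49f averaged 875 and 443. These levels stood out against the highest isotype control in the same cells, at 2.21 and 1.39 UMIs. T-like cells held 5.36 and 5.28 CD42b UMIs, 16.0 and 15.5 CD9 UMIs and 82.3 and 50.4 CD49f UMIs. Of these proteins, CD9 and CD49f are also made by leukocytes, whereas CD41 and CD42b belong to platelets. CD41 was 32.9 (31.7 to 34.2) and 10.2 (9.86 to 10.6) times higher on classical monocyte-like than on T-like cells, and CD62P 62.2 and 21.3 times.

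Unspecific binding of antibodies to monocytes is argued against, since the fold of the isotype controls between classical monocyte-like and T-like cells was at most 17.3% of the CD41 fold. Platelets caught in droplets at random are argued against as well, since they would reach all classes alike, while the smaller of the CD41 folds over T-like cells was 10.2. Platelets attached to monocytes may account for the pattern: classical monocyte-like cells above the class median of CD41 held 3.22 (2.99 to 3.47) times the platelet-gene RNA share of the rest in the 2-fold library and 1.66 (1.56 to 1.77) times in the 8-fold library. In the 8-fold library the relation held for PPBP, PF4, NRGN and CLU, while the intervals of GNG11, TUBB1, GP9 and RGS18 included 1, so it is uneven there. Classical monocyte-like cells also held more of these antibodies than platelet-like cells, in both libraries. CD62P averaged 286 and 106 UMIs against 52.2 and 13.0. CD41 averaged 111 and 35.8 against 91.2 and 26.8, and CD61 105 and 36.9 against 83.4 and 24.3. What this excess means for attached platelets was not tested. No biological explanation was tested, since the design names no group other than dilution, and whether any attachment arose in blood or during handling stays open.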

How the results depend on the processing

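The alternatives that thin to an equal median, leave B-like cells with more than 5 CD3 UMIs out of the thresholds, or leave out the 5% of cells with the most RNA UMIs, and for the AUC the top 1% of ADT cells, were chosen after seeing the data. A value is called the same when it lies within the main value's 95% interval, or for a gene set within as wide a range as its random lists span, and for a count within 1.5-fold. By this rule 18 of 43 main results were the same in every alternative run for them, among them the ratio of median ADT UMIs per cell (2.61 to 2.67), the median positive-class ratio (3.80 to 3.89), the median negative-class ratio (1.08 to 1.15), the number of antibodies with a higher AUC in the 2-fold library (35 to 39) and the median protein-RNA correlations (0.427 to 0.473 and 0.358 to 0.388). Over all alternatives, 292 values of main results were the same, 63 moved and 3 reversed; for named antibodies, genes and remaining sets, 1276 were the same, 102 moved and 20 reversed. Values for T-like clusters were computed in 1 setting only. Dilution cannot be told apart from batch. ADT sequencing depth alone would move the positive and the negative class of an antibody alike. Their median ratios were 3.87 and 1.12, with the positive class higher for 40 of 40 lineage antibodies. For these antibodies that argues against depth alone, but any part that depth has in the ratios cannot be separated. Several gene counts were decided by 5 or fewer cells. No paired analysis was possible because each group holds 1 library. Unless a cause is named, the cause was not tested.

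Among T-like cells only, the median antibody ratio was 1.30, CD11c 0.900, CD32 0.790 and the isotype controls had a median of 1.00 and a range of 0.953 to 1.14, with Mouse-IgG2a-k at 0.975 and Rat-IgG2c-k at 0.958, and the isotype shares were 0.256% and 0.429%. Without the top 1% of ADT cells, CD354 was 2.37 and CD85j 2.06, since 1 cell was removed that held most of both, and the isotype share of the 8-fold library was 0.508%. As shares of the library's ADT total, the median was 1.096, CD146 0.471, CD223 0.513, CD169 0.519 and CD71 0.486, and the isotype controls Mouse-IgG2a-k 0.489, Mouse-IgG2b-k 0.517, Rat-IgG2c-k 0.528 and ArmenianHamster-IgG 0.522. The cell that held most of CD85j and CD354 raised these ratios, since it held 15.7% of the ADT UMIs of the 8-fold library.

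Shares of classes moved as follows. Platelet-like cells were 4.73% of the 2-fold library with every barcode and 4.84% at resolution 2. With doublets kept, NK-like cells were 14.6% and 15.5%, and T-like cells 53.8% of the 8-fold library. NK-like cells were 15.6% of the 8-fold library at resolution 2.

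CD4-positive T-like cells of the 8-fold library were 8.96% with every barcode, 46.3% with a stricter filter on cells (under 10% mitochondrial UMIs; its higher minimum of genes removed no barcode), 9.35% with doublets kept, 79.9% at the 95th percentile, 75.9% with a Gaussian mixture (74.4% in the 2-fold library) and 79.9% without the B-like cells with CD3. CD8-positive cells of the 8-fold library were 21.1% at the 95th percentile and 21.1% with the mixture.

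With the stricter filter, gate matches in the 8-fold library were 94.8% for NK-like cells. NK-like matches were 85.3% and 84.9% with doublets kept, and 86.0% and 84.9% at resolution 2, in the 2-fold and 8-fold libraries. In the 2-fold library, T-like and classical monocyte-like matches were 97.0% and 85.3% thinned to an equal mean, 96.6% and 90.3% thinned to an equal median, and 95.9% and 90.7% with libraries clustered separately. At the 95th percentile, the 2-fold library had 92.8% (T-like) and 92.8% (NK-like), and the 8-fold library 86.8% (T-like) and 90.1% (NK-like). With the mixture, T-like and NK-like matches were 82.1% and 87.7% in the 2-fold library and 43.7% and 46.4% in the 8-fold library, where classical monocyte-like cells had 66.5%. Without the B-like cells with CD3, T-like matches in the 8-fold library were 91.3% and classical monocyte-like ones 66.5%, by the lower CD3 threshold that this leaves.

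Among gene sets (median log2, 8-fold over 2-fold), every barcode gave -0.34 for platelet genes in B-like cells, and -0.17 for interferon, -0.12 for inflammatory and 1.58 for cytotoxic genes in classical monocyte-like cells. The stricter filter gave -0.17 for cytotoxic genes in T-like cells and 0.17 for platelet genes in NK-like cells, within the wide range of that small set. Doublets kept gave -0.0064 for naive T genes in NK-like cells, -0.33 for platelet genes in B-like cells and 1.06 for cytotoxic genes in classical monocyte-like cells, with GZMB at -0.38 and PTGDS at -2.14 there. Resolution 0.5 gave -0.016 for ribosomal and 1.13 for cytotoxic genes in classical monocyte-like cells, with GZMB at -0.36 and PTGDS at -2.15. Resolution 2 gave -0.24 for cytotoxic genes in T-like, 0.075 for naive T genes in NK-like and -0.26 for inflammatory genes in classical monocyte-like cells. Separate clustering gave 0.0015 for ribosomal genes in T-like and -0.41 for platelet genes in classical monocyte-like cells. At least 100 UMIs gave 0.16 for naive T genes in B-like cells, and -0.19 for inflammatory and 1.52 for cytotoxic genes in classical monocyte-like cells. Equal weight per cell gave -0.0048 for cytotoxic genes in T-like cells, and 1.15 for cytotoxic, -0.54 for platelet and -0.014 for interferon genes in classical monocyte-like cells. CPM without ribosomal and mitochondrial genes gave -0.028 for ribosomal genes in T-like cells. Without the 5% of cells with the most RNA UMIs, cytotoxic genes in T-like cells were at 0.0056, ribosomal and platelet genes in classical monocyte-like cells at -0.012 and -0.56, and TXNDC5 and XBP1 in B-like cells at 0.15 and 0.47.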

Other observations

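All tests of this part except those on T-marker RNA and on CD3D, CD3E and CD3G were chosen after the results were seen, and the limits of 5 CD3 UMIs and 50 cytotoxic UMIs were set after seeing the values.

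Dendritic-like cells could be compared in the 8-fold library only, where 14 of them allowed a value. There the high-affinity IgE receptor FceRIa gave 16.5 UMIs per dendritic-like cell against 1.16 per T-like cell, a fold of 14.3 (12.4 to 16.4) and an AUC of 0.965. CD1c, which presents lipids, gave 2.14 against 0.209 UMIs, a fold of 10.2 (6.77 to 15.02), with a median of 1 UMI and 21.4% of the 14 cells above the 99th percentile of T-like cells. CD57, a protein of late-stage cytotoxic cells, was 5.43 (4.66 to 6.30) times higher in the regulatory cluster 9.2 than in other T-like cells in the 2-fold library, which had 22 such cells with a median of 0.5 UMIs, and 0.827 (0.585 to 1.14) times in the 8-fold library; this was not followed up. The cycling sub-cluster, with MKI67, TOP2A and RRM2 among its top genes, had 2 cells in the 2-fold library and 10 in the 8-fold library. TXNDC5, a gene of antibody-secreting cells, was also among its top genes, with UMIs in 2 and 3 of these cells; whether these are antibody-secreting cells was not tested.

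In the 8-fold library, 27.6% of T-like cells fell in the T gate against 98.4% in the 2-fold library. A lower CD3 signal was examined by thinning the CD3 counts of the 2-fold library to the T-like mean of the 8-fold library. With the threshold set anew, 95.5% (90.8 to 96.5 over random draws) of its T-like cells stayed in the gate. The thinning also lowered the B-like counts, whereas B-like cells held 0.707 CD3 UMIs in the 2-fold and 0.954 in the 8-fold library. It therefore cannot decide about a lower signal over an unchanged background. B-like barcodes that also held a T cell are a candidate explanation: the 4 B-like cells with more than 5 CD3 UMIs held 17.9 (9.98 to 32.1) times the CD3D, CD3E and CD3G RNA share of other B-like cells, with a UMI of these genes in 3 of the 4. That test was added only after one on all T markers had left the question open at 1.60 (1.37 to 1.87) times, where LTB, which B cells also express, made up 88.6% of the T-marker UMIs of other B-like cells. It rests on 26 UMIs in 4 cells.

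Cytotoxic genes were higher in classical monocyte-like cells of the 8-fold library. Free RNA of NK cells is argued against, since the 5 cells with the most cytotoxic UMIs held 64.8% of those UMIs, 22.8 times their share of RNA UMIs. Droplets with a monocyte and an NK cell may account for the pattern: the 5 cells with at least 50 cytotoxic UMIs carried 52.6 CD56 UMIs on average against 1.96 in the rest, 26.8 (23.2 to 31.0) times as many. Their median CD14 count was 8, as in the rest, and their median RNA total 16321 against 8032 UMIs. Without the 5% of cells with the most RNA UMIs, the cytotoxic median was still log2 1.96 (percentile 100, 10 of 11 higher). How many of the 5 cells this left out was not determined. No biological explanation was tested, since batch and dilution are the same split.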
